A study of Mus musculus with 6 samples.

How the data were processed

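Small RNA was measured in 6 libraries from male mouse hearts, 3 from sham hearts and 3 from hearts that underwent ischemia and reperfusion (I/R). Per the labels' protocols, every heart was perfused on a Langendorff system, which keeps an isolated heart supplied through the aorta. Sham hearts kept beating, while I/R hearts were arrested with cardioplegia, a solution that stops contraction, for 30 min and then reperfused for 1 h. The labels number the biological replicates 1 to 3 in each group, and groups and numbers were taken from them. The library protocol in the labels describes poly(A) mRNA kits, although the titles call the libraries miRNA-seq.

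The deposited table gives 1 signal value per mature miRNA and library, and its name calls the values FPKM. It lists 1978 mouse miRNA names and 31 names for predicted miRNAs. Per the submitters' processing notes, bcl2fastq 2.19.1.403, fastp 0.23.0 and the mm10 genome were used. The aligner, the miRNA annotation, the strand setting and the treatment of reads that match several loci are not given in the sources used here. Checked on the values, the 6 deposited signal columns summed to the same total, and every value in a column was a whole multiple of that column's smallest value above 0. Such values are read counts times 1 factor per library, as counts per 1000000 reads (RPM) divided by a constant length of 23.0 nt for every miRNA would be. The design had been written for FPKM with a length per miRNA; the test on log values fits either unit and was kept. Division by the step recovered whole reads for 100% of the values in each library, with a tolerance of 0.01 reads. Levels are given as RPM.

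The recovered depth was 9197869, 8847867 and 8099411 reads in sham replicates 1 to 3 and 8196102, 8177824 and 7874103 reads in I/R replicates 1 to 3. A limit of 3 reads corresponded to 0.326 to 0.381 RPM. Reads were not collapsed to molecules in any source used here, so counting limits cover counting error only. Pearson's correlations of log2 levels across miRNAs, which are not independent replicates, were 0.990 to 0.996 between libraries. No 2 libraries of a group agreed within sampling noise, with chi-square values of 33.3 to 132 per degree of freedom.

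Changes between I/R and sham were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(signal + 43.5), where 43.5 is the signal of 1 RPM, without further scaling. A fold change on this scale understates the change of low miRNAs. Names were kept with a mean of at least 1 RPM and a value above 0 in at least 3 of the 6 libraries, whatever their group, which left 409 names that held at least 99.98% of the reads of each library. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. The balance of the 2 arms of a precursor was tested in the same way on the log2 ratio of the 5p to the 3p arm, in 94 precursors with both arms kept. Lists of miRNAs were tested with camera in limma, with a preset correlation of 0.01 and beside it an estimated one, and with fry, for the 16 lists with at least 3 kept members. Library composition was compared with two-sided exact permutation tests, for which 0.1 is the smallest p that 3 against 3 libraries allow.

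The test, filter, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took the 5 most abundant miRNAs, up to 10 passing miRNAs per direction, otherwise up to 5 per direction with the smallest p among those whose groups did not overlap, 3 members of each passing list with the smallest p, 10 miRNAs named in advance, and 3 precursors per direction for arm balance. The 16 lists were muscle, red blood cell, leukocyte, endothelial, fibroblast and smooth muscle, other tissue, hypoxia-linked and inflammation-linked miRNAs, the miR-34, miR-15/16, let-7, miR-30 and miR-29 families, and the miR-17/92, Dlk1-Dio3 and Sfmbt2 clusters.

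Both groups carry replicate numbers 1 to 3. Deviations from the group means correlated at 0.14, 0.28 and 0.16 between libraries with the same number, all above 0.1, and at -0.19 to 0.07 between libraries with different numbers. The numbers were therefore taken to pair the libraries, from the data alone. The labels do not state that a number marks a shared day or batch. Deviations cancel out within a group, so high correlations for same numbers pull the others down, and the contrast is weak support. There are few ways to match 3 libraries with 3, so same numbers can also correlate best by chance. No other matching was fitted. Tests with the block used the same data, so their p-values are conditional on the pairing by number. A fit with the replicate number as a block had been listed as an alternative, and its values stand beside the results it changes.

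Other alternatives were the pseudocount, the filter, 4 scalings of the libraries, limma's robust, untrended and array-weighted fits, and each library left out in turn. Added after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, edgeR with the block, the block without each pair, the block with median-ratio scaling, a fit with names that share reads summed, and the scalings applied to arm balance. Precursor positions came from GENCODE M21 on GRCm38, the assembly also called mm10, with name synonyms from RefSeq, and 392 of the 409 kept names had a locus.

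The scripts were tested on 200 simulated data sets of 3 and 3 libraries with the recovered depths and spread for I/R against sham. With 200 of the 409 miRNAs changed per data set, 82.1% of 2-fold, 48.5% of 1.5-fold and 99.0% of 4-fold changes were called, as were 2.27% of unchanged miRNAs. That many changes ease the adjusted threshold, and with 6 of the 409 changed the shares were 57.6%, 13.0% and 92.7%, and 0.135% of unchanged miRNAs. Without any change, 14.0% of the data sets gave at least 1 call, 24.5% did with the block, and 3.00% gave 4 or more calls with the block. Each miRNA was drawn independently and without an effect of the replicate number, so these shares may not hold for miRNAs that vary together. Long RNA libraries of the same study were not analysed here.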

Results

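The series profiled miRNAs, short RNAs that repress their target mRNAs, in mouse hearts after cardioplegic arrest and reperfusion, a model of the injury that can follow heart surgery on bypass. It compared 3 I/R hearts, with 30 min of arrest and 1 h of reperfusion, with 3 sham hearts that were perfused but not arrested. The libraries held 7874103 to 9197869 reads on named miRNAs, and 799 to 867 miRNAs lay above 0 per library. Values are means ± SD in RPM with n = 3 hearts per group.

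The profile was dominated by miR-1a, a muscle-specific miRNA of heart and skeletal muscle. The name miR-1a-3p held 380232 ± 2375 RPM in sham and 365121 ± 12373 RPM in I/R hearts (n = 3 each), and miR-1b-5p, listed beside it, held 190133 ± 1446 and 182563 ± 6174 RPM. The next most abundant were miR-99a-5p with 79240 ± 5374 and 80529 ± 2656 RPM, miR-143-3p, a miRNA of vascular smooth muscle, with 40066 ± 5843 and 44146 ± 4847 RPM, and miR-126a-3p, an endothelial miRNA, with 25563 ± 1278 and 27683 ± 3196 RPM. None of these 5 names passed the test, with limma log2 fold changes of -0.06 for both miR-1 names (SE 0.04), 0.03 for miR-99a-5p (SE 0.06), 0.14 for miR-143-3p (SE 0.11) and 0.11 for miR-126a-3p (SE 0.09), adjusted p from 0.661 to 0.893. The sign for miR-99a-5p turned under other scalings, and that for miR-126a-3p only in edgeR with TMM. The miR-1a hairpins lie on chromosome 2 at 180389048 to 180389124, outside annotated host genes, and on chromosome 18 at 10785481 to 10785552, in an intron of Mir133a-1hg and opposite to Mib1. The miR-1b hairpin lies on the opposite strand of chromosome 18 at 10785446 to 10785567, in an intron of Mib1 (GRCm38).

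The names miR-1a-3p and miR-1b-5p held reads in a fixed ratio, so their values are uncertain taken singly. The share of miR-1a-3p in their sum was 66.7% over all libraries (95% Wilson interval 66.6% to 66.7%), from 66.6% to 66.7% per library, which is the ratio of 2 loci to 1. Together both names held 57.0 ± 0.38% of the reads in sham and 54.8 ± 1.85% in I/R hearts (n = 3 each). The groups did not overlap, and the difference of -2.27 percentage points gave exact permutation p = 0.1, the smallest that 3 against 3 hearts allow. The muscle list, which holds miR-1a-3p but not miR-1b-5p, held 38.8 ± 0.23% and 37.2 ± 1.29% of the reads (exact p = 0.1), and the 10 most abundant miRNAs held 81.9 ± 0.17% and 80.9 ± 0.70% (exact p = 0.1). Much of each difference came from I/R replicate 3, without which the 3 differences of -2.27, -1.54 and -0.921 percentage points were -1.25, -0.836 and -0.538. The last 2 measures were among 5 fixed in advance and have an adjusted p of 0.25 over these, while the sum of the miR-1 names was chosen after the values were seen and was not adjusted.

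Other miRNAs whose hairpins lie on opposite strands of 1 locus also held reads in fixed ratios, so each of them is uncertain taken singly. miR-24-3p, a miRNA abundant in heart, held 50.04% of its sum with miR-3074-5p, and miR-486a-5p held 49.99% of its sum with miR-486b-3p. Of the 6 such pairs with a mean of at least 1000 reads per name, a chi-square test of the reads found no difference in share between libraries in 6. The same was found for 30 of 5256 other pairs of names at that depth (0.571%). The identical sequences miR-199a-3p and miR-199b-3p, from 2 loci and 1 locus, stood at a share of 66.7%. miR-126a-3p held 99.8% of its sum with miR-126b-5p and was the exception among the abundant miRNAs.

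**Figure D1:**
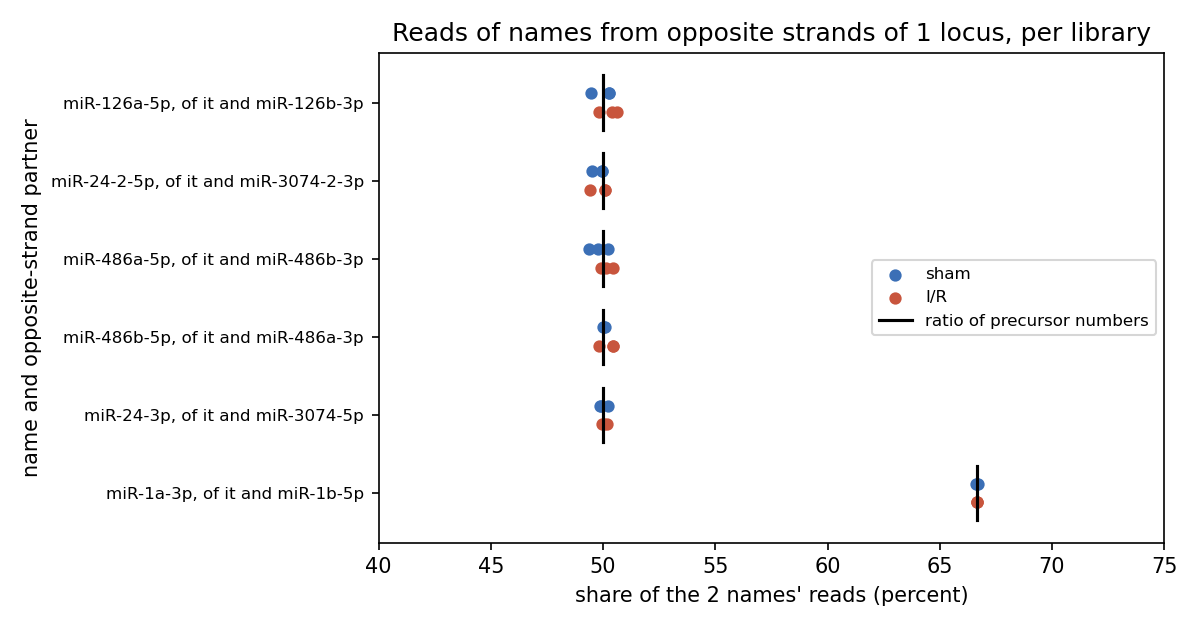
Share of the first name in the summed reads of 2 names from opposite strands of 1 locus (horizontal axis, percent, from 40 to 75), per sham (blue) and I/R (red) library, for 6 pairs (vertical axis). Black bars mark the ratio of precursor numbers, 66.7% for miR-1a-3p and 50% for the others, and pooled shares lie within 0.161 percentage points of it.

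The lists of blood cell miRNAs held a small part of the reads in both groups. The red blood cell list held 0.311 ± 0.033% of the reads in sham and 0.331 ± 0.042% in I/R hearts (exact permutation p = 0.7, adjusted p = 0.875). Nearly all of it was miR-486a-5p and miR-486b-5p, from the Ank1 locus. Whether these reads came from red blood cells was not tested, so the share is no measure of blood content. Leukocyte miRNAs held 0.0143 ± 0.0021% and 0.0144 ± 0.0004% (exact permutation p = 1, adjusted p = 1). The number of miRNAs above 0 was 822 ± 21 and 842 ± 30 (exact permutation p = 0.4, adjusted p = 0.667). The erythroid miR-451a was at 4.72 ± 1.52 and 2.75 ± 1.78 RPM, and the leukocyte miR-142a-3p at 1.23 ± 0.28 and 1.19 ± 0.49 RPM.

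The main comparison asked which miRNAs differ after I/R. The highest fold changes with separate groups were those of miR-5103, from 45.1 ± 12.6 to 125 ± 43.8 RPM (log2 fold change 1.43, SE 0.29, n = 3 each), and miR-6240, from 7.45 ± 1.72 to 18.4 ± 8.78 RPM (1.14, SE 0.29). Neither passed the threshold in limma (adjusted p = 0.370 and 0.598), and of 409 miRNAs 0 were higher and 0 lower at that threshold. At an unadjusted p under 0.05 there were 29 higher and 1 lower, edgeR called 0 with 26 at an unadjusted p under 0.05, and DESeq2 called 2, miR-5103 and miR-6240. Without sham replicate 2 limma called miR-27a-5p (adjusted p = 0.0161), chosen after its value was seen, and without a filter it called miR-5103 (adjusted p = 0.0433). Levels of the groups did not overlap for 46 higher and 16 lower miRNAs, 15.2% of those tested, where chance gives 10%.

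With the replicate number as a block, 4 miRNAs rose and 0 fell. All 4 are among the 37 kept names that have no arm ending. That the numbers pair the libraries rests on these same data, and the p-values with the block are conditional on it. limma's adjusted p with the block was 3.3e-05 for miR-5103 and 0.00458 for miR-6240. The other calls, miR-3968 and miR-3963, fell outside the naming rule and were chosen after their values were seen. miR-3968 went from 267 ± 91.3 to 462 ± 165 RPM (log2 fold change 0.79, limma adjusted p with the block 0.00108), and miR-3963 from 176 ± 56.3 to 294 ± 125 RPM (0.71, limma adjusted p with the block 0.00458). In each of the 3 pairs all 4 were higher in the I/R heart, by 0.54 to 1.71 on the log2 scale. The block fit picks names with such rises, so this is no separate evidence. The hairpin of miR-5103 lies on chromosome 1 at 34433121 to 34433199, in an exon of the lincRNA Gm37233. That of miR-6240 lies on chromosome 5 at 114851948 to 114852064 and that of miR-3963 on chromosome 3 at 151023792 to 151023862, both outside the annotated protein-coding and long noncoding genes searched, and that of miR-3968 on chromosome 11 at 115447961 to 115448060, opposite to Trim80.

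**Figure D2:**
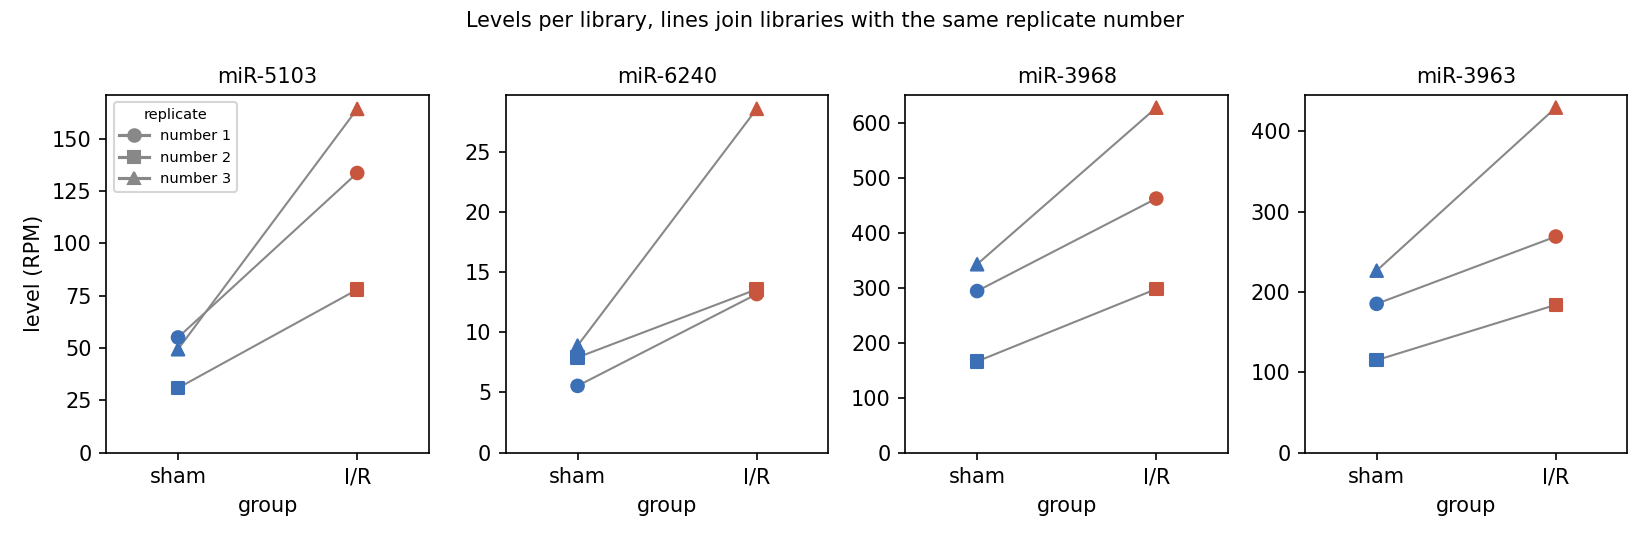
Level in RPM (vertical axes, linear, starting at 0) of the 4 miRNAs that rose in I/R with the replicate block, in sham (blue) and I/R (red) libraries. Lines join libraries with the same replicate number, and all 12 lines go up, by 0.54 to 1.71 on the log2 scale. The names were picked by the fit with this pairing, so the rises are no separate evidence.

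The other miRNAs with separate groups did not pass in limma, and those with the smallest p, up to 5 per direction with the 2 above, are named here. On the higher side they were miR-99b-3p (46.0 ± 1.66 and 63.2 ± 7.46 RPM in sham and I/R), miR-370-3p (10.9 ± 0.81 and 15.3 ± 1.36 RPM) and miR-200b-3p, an epithelial miRNA (1.68 ± 0.30 and 3.01 ± 0.28 RPM). The lower side held miR-365-3p (3.56 ± 1.94 and 1.56 ± 0.48 RPM), miR-874-3p (10.9 ± 0.84 and 8.41 ± 1.14 RPM), miR-872-3p (3.28 ± 0.55 and 2.07 ± 0.75 RPM), miR-700-5p (2.18 ± 0.27 and 1.35 ± 0.47 RPM) and let-7f-5p (14494 ± 702 and 13308 ± 270 RPM). Their limma log2 fold changes were 0.45, 0.45 and 0.59 on the higher side and -0.77, -0.34, -0.51, -0.45 and -0.12 on the lower side, with adjusted p of 0.598 to 0.628. The size for the scarce ones depended on the pseudocount, and with 10 times as much it was 0.27 for miR-370-3p, 0.16 for miR-200b-3p, -0.22 for miR-365-3p, -0.18 for miR-874-3p, -0.14 for miR-872-3p and -0.10 for miR-700-5p.

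miRNAs often studied in the injured heart stayed below the threshold. miR-21a-5p, a miRNA linked to fibrosis, was at 21588 ± 2271 RPM in sham and 25370 ± 3374 RPM in I/R (log2 fold change 0.23, 95% interval -0.02 to 0.48, n = 3 each). The hypoxia-induced miR-210-3p was at 88.9 ± 5.53 and 86.0 ± 6.44 RPM (-0.05, interval -0.32 to 0.22). miR-208a-3p, encoded in an intron of the heart myosin gene Myh6, was at 169 ± 10.3 and 157 ± 11.2 RPM (-0.10, interval -0.36 to 0.15), and miR-499-5p, encoded in an intron of Myh7b, at 5602 ± 354 and 5679 ± 500 RPM (0.02, interval -0.18 to 0.22, with the sign turned under other scalings). miR-133a-3p was at 1231 ± 493 and 919 ± 108 RPM (-0.36, interval -0.89 to 0.17) and the liver miRNA miR-122-5p at 3.37 ± 0.28 and 3.96 ± 0.33 RPM (0.18, interval -0.20 to 0.57). Adjusted p in limma was 0.598 to 0.955 for these 6, 0.628 for miR-451a (log2 fold change -0.68) and 0.968 for miR-142a-3p (-0.04). For 373 of the 409 miRNAs (91.2%) the 95% interval lay inside a 2-fold change in either direction. These intervals are on the scale with the pseudocount, which understates the change of low miRNAs. For scarce names they therefore do not exclude larger changes of the level itself.

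The fold changes were not centred on 0. Of the 409, 287 were positive and 122 negative, with a median of 0.10 on the log2 scale. The split of 29 higher and 1 lower at an unadjusted p under 0.05 became 15 and 12 with median-ratio scaling, 10 and 6 with quantile normalization, 16 and 6 with totals taken without the 10 most abundant miRNAs, and 11 and 15 in edgeR. The median moved by -0.10, -0.11, -0.07 and -0.11 under these. The deposited totals were equal, so the lower share of the miR-1 names in I/R, 54.8% against 57.0%, raises the share of the other names together. The 287 positive names are therefore no sign of a general rise, and how much of the shift this explains was not tested.

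**Figure D3:**
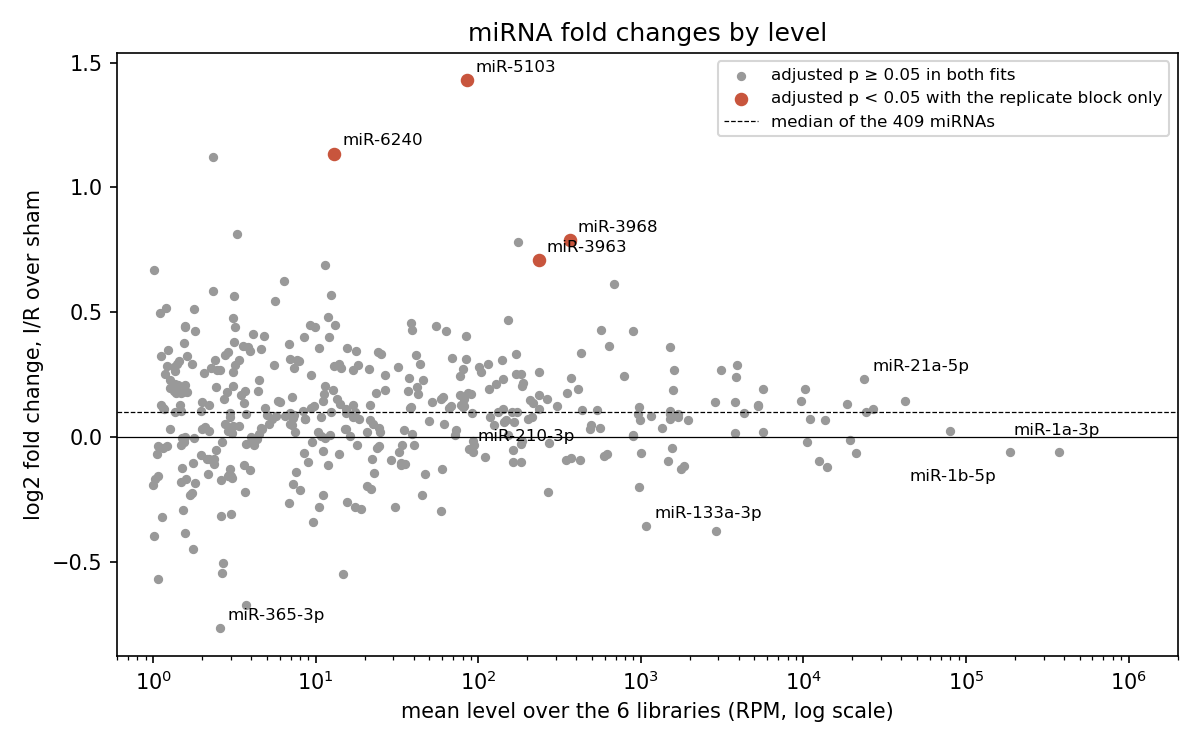
Log2 fold change of I/R over sham (vertical axis) against the mean level over 6 libraries in RPM (horizontal axis, log scale) for 409 miRNAs. Red points are the 4 miRNAs with limma adjusted p under 0.05 with the replicate block, grey points passed in neither limma fit, and the dashed line is the median of 0.10.

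Among the lists, the Dlk1-Dio3 cluster was shifted upward. This cluster is a large imprinted group of miRNAs expressed from the maternal chromosome. All 22 kept members of the 42 named had positive fold changes, with a median of 0.32 on the log2 scale, and 19 lay above the median of all miRNAs. In sham and I/R hearts, miR-127-3p was at 561 ± 75.8 and 720 ± 63.7 RPM (log2 fold change 0.36, SE 0.13, n = 3 each), miR-541-5p at 54.0 ± 5.86 and 73.1 ± 10.5 RPM (0.43, SE 0.15) and miR-370-3p at the levels above. The members together held 1194 ± 192 and 1525 ± 168 RPM. The 19 precursors found lie on the plus strand of chromosome 12 between 109585789 and 109743496 (GRCm38), with that of miR-370 in an intron of Rian, that of miR-541 in an intron of Mirg and that of miR-127 opposite to Rtl1. The list passed camera in limma at adjusted p = 0.00138, but with an estimated correlation the adjusted p was 0.651 and in fry 0.490, and no member passed over all miRNAs or adjusted over the list alone. Without sham replicate 1 the median was 0.16 and limma's camera adjusted p 0.0933, and with 10 times the pseudocount the median was 0.17 and the list still passed.

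The muscle miRNAs, enriched in heart and skeletal muscle, were shifted downward. Of the 8 members 7 had negative fold changes, all 8 lay below the median of all miRNAs, and the list median was -0.10 on the log2 scale. Besides miR-1a-3p and miR-133a-3p, miR-206-3p was at 12.1 ± 1.68 RPM in sham and 10.1 ± 0.39 RPM in I/R hearts (log2 fold change -0.23, SE 0.15, n = 3 each). The list passed camera in limma at adjusted p = 0.00177, with adjusted p = 0.603 under an estimated correlation and 0.490 in fry, and without I/R replicate 3 the camera adjusted p was 0.113. No member passed over all miRNAs or adjusted over the list alone.

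The miR-30 family, abundant in heart muscle, also passed on the lower side. Its 5 members lay below the median of all miRNAs, 4 with negative fold changes, with a list median of -0.07. In sham and I/R hearts (n = 3 each), miR-30e-5p was at 1846 ± 53.4 and 1688 ± 82.9 RPM (log2 fold change -0.13, SE 0.08), miR-30b-5p at 64.8 ± 11.2 and 53.2 ± 13.8 RPM (-0.30, SE 0.20) and miR-30d-5p at 21439 ± 1868 and 20428 ± 470 RPM (-0.07, SE 0.07). Camera in limma gave adjusted p = 0.0337, with adjusted p = 0.651 under an estimated correlation and 0.490 in fry. The call was lost without sham replicate 1 or 3 and without I/R replicate 1 or 3, with adjusted p of 0.121, 0.129, 0.0863 and 0.312, and without a filter, with 0.126. No member passed over all miRNAs or adjusted over the list alone.

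The other 13 lists did not pass, and none of their members passed over all miRNAs or adjusted over the list alone. Medians on the log2 scale were 0.18 for 10 fibroblast and smooth muscle miRNAs, 0.15 for 10 miRNAs of other tissues, 0.19 for 8 inflammation-linked miRNAs, 0.21 for 3 miR-34 miRNAs, 0.08 for 4 endothelial and 12 hypoxia-linked miRNAs, 0.09 for 8 miR-17/92 and 3 red blood cell miRNAs, 0.06 for 6 miR-15/16 miRNAs and 0.02 for 5 Sfmbt2 miRNAs. They were -0.01 for 7 leukocyte miRNAs, -0.08 for 9 let-7 miRNAs and -0.09 for 3 miR-29 miRNAs. Camera adjusted p in limma was 0.0569 for let-7 and for miR-29, which passed under some other settings, and 0.525 to 0.920 for the rest. The sign of the median turned under another scaling for the endothelial, hypoxia-linked, miR-15/16, miR-17/92, red blood cell and Sfmbt2 lists, and the leukocyte list, with a median below and a mean above 0, turned with array weights. Camera compares a list with the other miRNAs, so its direction is not measured from 0. It pointed down for the red blood cell, miR-17/92 and Sfmbt2 lists, whose medians lay above 0 but below the median of all miRNAs. The red blood cell mean was -0.16.

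**Figure D4:**
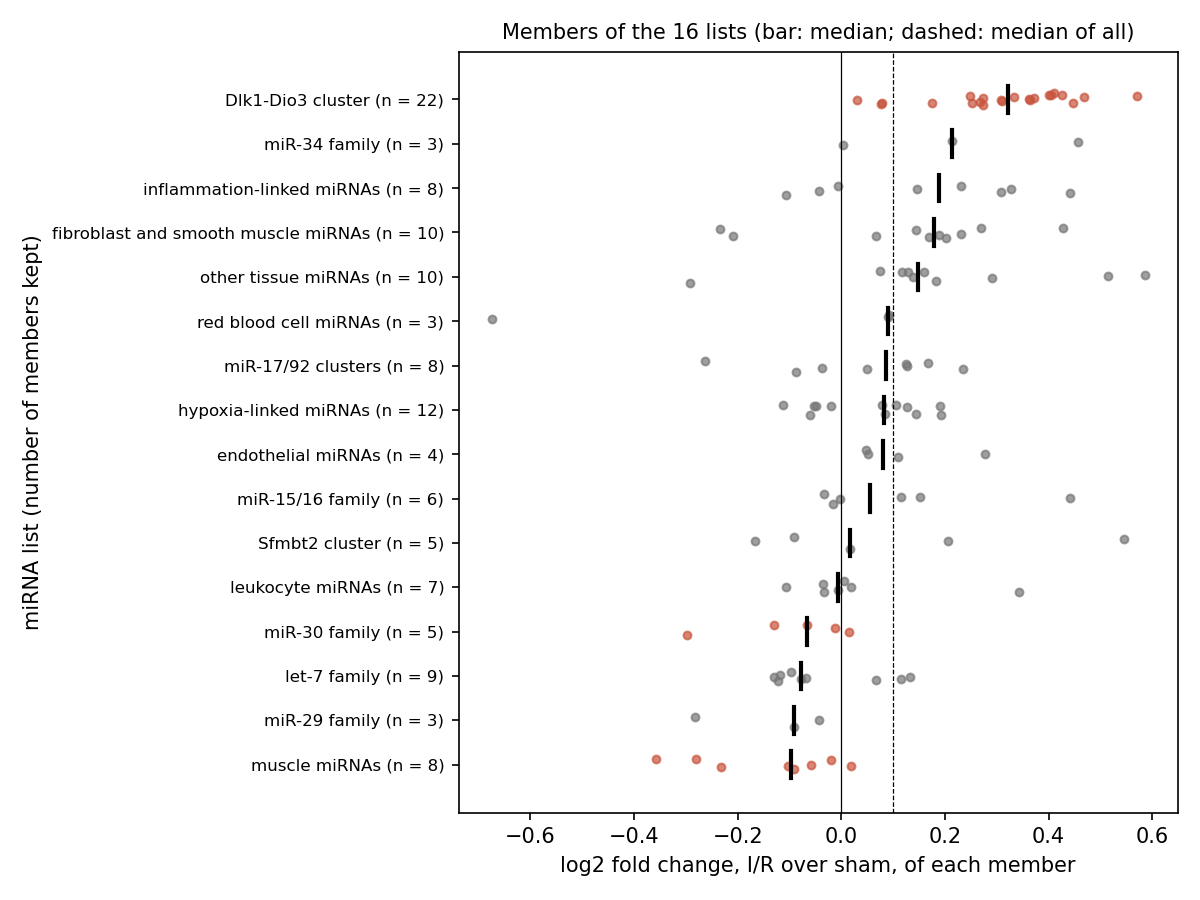
Log2 fold change of I/R over sham (horizontal axis) for each kept member (points) of the 16 lists (vertical axis, with the number of members). Bars are list medians, the dashed line is the median of all miRNAs, and red marks the 3 lists with camera adjusted p under 0.05 in limma, whose medians are 0.32, -0.07 and -0.10.

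Arm balance asks whether the 2 strands of a hairpin change against each other. The precursors with the smallest p toward the 5p arm were miR-872, where the log2 ratio of 5p to 3p was 4.06 ± 0.22 in sham and 4.81 ± 0.22 in I/R hearts (n = 3 each), miR-664 (0.27 ± 0.27 and 1.01 ± 0.17) and miR-5615 (-0.08 ± 0.16 and 0.58 ± 0.26). On the other side stood miR-700 (-2.31 ± 0.03 and -2.87 ± 0.25), miR-143 (-10.66 ± 0.20 and -11.01 ± 0.19) and miR-106b (-0.98 ± 0.30 and -1.43 ± 0.20). Of 94 precursors 0 passed in limma, where the smallest adjusted p was 0.190, and 6 had an unadjusted p under 0.05. The hairpins listed for miR-5615 overlap on opposite strands of chromosome 10. Reads of its 2 arms may therefore be mixed, and its ratio is uncertain.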

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

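The count models, edgeR with the block, the block without a pair or with median-ratio scaling, summed shared reads, the scalings for arm balance and left-out libraries for the miR-1 sum were chosen after seeing the data. Of 29 miRNAs named by the rule and 2 chosen after their values were seen (miR-3968 and miR-3963), 22 kept their direction under every alternative run, 6 changed sign under at least 1, and 3 others (miR-1a-3p, miR-1b-5p and miR-143-3p) came out at exactly 0 with quantile normalization, which gives a miRNA of the same rank in all libraries 1 value. The medians of 7 of 16 lists kept their sign. The count of called miRNAs was 0 under 18 of 27 alternatives, and that of precursors with changed arm balance under 23 of 23, where the smallest limma adjusted p was 0.183 to 0.466 under the scalings. Rescaling to the same total moved nothing, because the deposited totals were equal.

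The count of miRNAs higher in I/R was 4 with the replicate block, 4 with the block and median-ratio scaling, 4 in edgeR with the block, 2 in DESeq2, and 1 without a filter (miR-5103), where 1259 names were tested. It was 0 to 1 with 1 library left out, the 1 being miR-27a-5p without sham replicate 2 (limma adjusted p = 0.0161). With the block, 7 were higher and 1 lower without pair 1, 21 and 4 without pair 2, and 6 and 2 without pair 3, so fewer libraries gave more calls. The block changed no list or arm call.

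The count of lists past the threshold was 3 and became 5 with the filter at 10 RPM, with median-ratio scaling, with totals without the 10 most abundant miRNAs and with the block and median-ratio scaling. It became 1 with the block without pair 1 or pair 3, 1 to 3 with 1 library left out, and 0 with the estimated correlation (smallest adjusted p 0.603) and in fry (0.490). The Dlk1-Dio3, muscle and miR-30 medians of 0.32, -0.097 and -0.066 then no longer passed, nor did miR-30 (-0.066) without a filter. Over the left-out libraries, the medians were 0.16 to 0.39, -0.19 to -0.056 and -0.12 to -0.048. The let-7 median passed at -0.077 with the 10 RPM filter, -0.18 with median-ratio scaling and -0.15 without the top 10, passed at -0.12 without sham replicate 3 (adjusted p = 0.0409), and ranged from -0.12 to 0.016 over left-out libraries. The miR-29 median passed at -0.091, -0.19 and -0.16 under the same 3 settings, at -0.22 with quantile normalization and at -0.14 with array weights, passed at -0.18 without sham replicate 1 (adjusted p = 0.0173), and ranged from -0.18 to -0.041. Both also passed with the block and median-ratio scaling. Over all alternatives, camera adjusted p in limma ranged from 0.00304 to 0.651 for let-7 and from 0.0157 to 0.651 for miR-29.

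Medians of lists that did not pass changed sign. The median of all miRNAs also moved, by -0.10 with median-ratio scaling, -0.11 with quantile normalization and -0.07 without the top 10. Such a common shift can turn list medians just above 0, and the cause of the other changes was not tested. With median-ratio scaling they were -0.061 for Sfmbt2, -0.021 for endothelial and for hypoxia-linked, -0.028 for miR-15/16, -0.0061 for miR-17/92 and -0.012 for red blood cell miRNAs. With quantile normalization they were -0.096 for Sfmbt2, -0.0088 for endothelial, -0.069 for hypoxia-linked, -0.042 for miR-15/16 and -0.10 for miR-17/92. Without the top 10 they were -0.038 for Sfmbt2 and -0.0023 for miR-15/16, with array weights -0.038 for Sfmbt2 and 0.074 for leukocyte, with the 10 RPM filter 0.012 for leukocyte and -0.016 for miR-15/16, and without a filter -0.17 for red blood cell miRNAs. With 1 library left out they ranged from -0.034 to 0.17 for Sfmbt2, -0.085 to 0.11 for leukocyte, -0.032 to 0.28 for miR-15/16, -0.0082 to 0.14 for miR-17/92, -0.055 to 0.46 for miR-34 and -0.017 to 0.16 for red blood cell miRNAs. The difference in read share ranged from -0.00064 to 0.0013 percentage points for leukocyte and from -0.0039 to 0.036 for red blood cell miRNAs.

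The log2 fold change of miR-99a-5p changed sign to -0.078 with median-ratio scaling, -0.046 without the top 10, -0.0068 with array weights, -0.091 in edgeR, -0.090 in edgeR with the block and -0.075 in DESeq2. That of miR-499-5p became -0.085 with median-ratio scaling, -0.094 with quantile normalization, -0.053 without the top 10, -0.094 in edgeR, -0.097 in edgeR with the block and -0.079 in DESeq2. miR-126a-3p became -0.0030 in edgeR and -0.0048 in edgeR with the block. Over left-out libraries the ranges were -0.033 to 0.054 for miR-99a-5p, -0.053 to 0.064 for miR-499-5p, -0.20 to 0.12 for miR-142a-3p, -0.10 to 0.0012 for miR-210-3p and -0.12 to 0.0023 for miR-30d-5p, and the cause was not tested. With 10 times the pseudocount the log2 fold change was 0.67 for miR-6240, -0.21 for miR-451a, -0.13 for miR-206-3p, 0.063 for miR-122-5p and -0.0045 for miR-142a-3p, and with 0.1 times -0.69 for miR-700-5p and -0.081 for miR-142a-3p, while the miR-34 median was 0.036 and 0.44; no sign or call changed with either. Below 1 RPM, a level rests on fewer than 10 reads per library, and such names were not tested apart from the fit without a filter.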

Other observations

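Among 114 names with a mean of at least 100 RPM, the within-group spread was highest for miR-10b-5p and miR-10a-5p, whose genes lie in the Hox clusters. Among I/R hearts the highest level was 4.19 times the lowest for miR-10a-5p, with 2754 ± 1852 RPM (n = 3), and 3.47 times for miR-10b-5p, with 933 ± 524 RPM. Among sham hearts the factors were 1.37 and 2.16, below the 2.65 of miR-27a-5p. The within-group SD on the log2 scale was 0.77 for miR-10b-5p and 0.75 for miR-10a-5p, against a median of 0.11 over these 114 names. In both groups replicate 2 was the highest, at 1545 RPM in sham and 1470 RPM in I/R for miR-10b-5p and 3438 and 4775 RPM for miR-10a-5p. Part of the spread may thus follow the replicate numbers, which was not tested. These names, and those in the next paragraph, were chosen after their values were seen.

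miRNAs with neighbouring hairpins had very different read levels. Reads of different miRNAs were not calibrated against each other, so ratios of reads need not be ratios of molecules. miR-1a-3p had 339 ± 114 times the reads of miR-133a-3p in sham and 400 ± 35.3 times in I/R hearts (exact permutation p = 0.5, n = 3 each). Their hairpins neighbour each other on chromosomes 2 and 18, and reads of the 2 loci were not told apart. With the reads listed under miR-1b-5p added, the ratios were 509 ± 170 and 600.3 ± 53.05. The smooth muscle miRNA miR-143-3p stood at 876 ± 252 and 1115 ± 174 times miR-145a-5p (exact permutation p = 0.3).

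The tests of explanations below were chosen after the results were seen, although median-ratio scaling and left-out libraries had been planned as alternatives. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 0 miRNAs and the highest other 4, so 10 of 10 splits gave as many; at an unadjusted p under 0.05 it had 30 and the highest other 28. For arm balance the real split called 0 and the highest other 0, again 10 of 10. For lists the real split called 3 and the highest other 2, so 1 of 10 gave as many. Among the 4 splits that part all 3 pairs, also too few, the highest others had 0 miRNAs called and 12 at an unadjusted p under 0.05, 0 precursors and 1 list. The split with 4 calls, of sham replicates 1 and 3 and I/R replicate 1 against the rest, parted only 1 pair.

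The first pattern is the rise of miR-5103, miR-6240, miR-3968 and miR-3963 within replicate numbers. Scaling of libraries by their total as the whole cause is argued against by the block with median-ratio scaling, which called 4 of the 4 names. The block without each pair called at least 3 of the 4, but it cannot decide whether a single pair was the cause. With fewer libraries that fit called more miRNAs than with all pairs, so a call by it carries little weight. Fragments of other RNAs counted under names with no arm ending stay open. All 4 names are among the 37 of 409 kept names with no such ending. The 33 other such names had a median of 0.10, like all miRNAs. For them limma's camera with the block gave a p-value of 0.569, with 0.662 under an estimated correlation, which cannot decide. The 4 splits that part all 3 pairs are too few for a share under 0.05: the real one called 4, the highest other 0, and 1 of 4 gave as many. An effect of I/R may underlie the rise, which stays a hypothesis, and 3% of simulated data sets without any change gave 4 or more such calls. The simulation drew each miRNA independently and without an effect of the replicate number. For miRNAs that vary together the share may be higher. miR-3963 and miR-3968 did vary together, as both were lowest in replicate 2 and highest in replicate 3 of each group. Their calls may thus not be separate observations, and the simulated share does not cover this.

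The second pattern is the upward shift of the Dlk1-Dio3 list. Scaling by the library total moves all miRNAs of a library almost alike, and camera compares the list's members with the other miRNAs. With median-ratio scaling the list's median was 0.23 against 0.01 for all miRNAs. limma's camera adjusted p was then 1.0e-04 (range over all alternatives 1.0e-04 to 0.651). Rescaling could hardly have removed this call, so the call does not decide whether scaling contributed. A trend with abundance is argued against by 10000 lists matched on mean level, of which 0% had a median as high as 0.32. A single library, sham replicate 1, is a candidate explanation for part of the shift, since without it the median was 0.16 and camera's adjusted p 0.0933 in limma. In sham replicate 1 the list's members lay at -0.42 on the log2 scale against their means over all libraries, compared with -0.10 for all miRNAs there. In I/R replicate 3 they lay at 0.33 compared with 0.13. The other libraries lay closer together, with 0.005 and -0.056 in sham replicates 2 and 3 and 0.036 and 0.14 in I/R replicates 1 and 2. Among the 4 splits that part all 3 pairs, too few for a share under 0.05, 1 gave a camera p as small as the real 8.6e-05, the smallest other being 0.0308. Of all 10 splits 2 did, the real one and another at 7.4e-05. A further split came close with a camera p of 9.7e-05, and both of these others parted only 1 pair. An effect of I/R stays open and untested apart from this.

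The third pattern is the constant ratio of names on opposite strands. If reads were placed at random among matching loci on either strand, pooled shares would equal the ratio of locus numbers, and for the 6 pairs the largest distance was 0.161 percentage points, so that counting without strand may account for it. miR-9-5p departs from this, at 49.5% of its sum with miR-9b-3p where 3 annotated loci to 1 would give 75%, and miR-126a-3p at 99.8% where 50% would be given. No biological explanation was tested.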
